A study of Mus musculus with 4 samples.

How the data were processed

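Ago2 PAR-CLIP libraries were made from Abelson-virus-transformed B cell progenitor lines of mouse fetal liver at embryonic day 14.5, of C57BL/6 background, 2 wild type and 2 homozygous for a mutated Bim 3' UTR. Per the labels' protocols, cells were given 500 µM 4-thiouridine for 5 hours and crosslinked at 365 nm, Ago2 was precipitated with an antibody, and bound RNA was trimmed with RNase T1 at 10 U/µl for 10 minutes. Per the submitters' processing notes, the authors used CASAVA 1.8.2, BWA 0.7.12-r1039 and DESeq2, whose version is not given, with the builds mm9 and NCBIM37. The roles, settings and read filters, and how features were defined and counted, are not given in the sources used here. Removal of PCR copies is likewise not given, so reads may include copies of one molecule.

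The data analysed were 1 table of the authors' own comparison, with no values per library. Per the file headers, the first value column is the mean of reads divided by size factors over all 4 libraries, a normalized signal computed by the authors with DESeq2. The second, per the file headers, is a log2 fold change from the authors' fit, and its direction, mutant over wild type, was taken from the deposited table's name. The third is the authors' unadjusted p-value, as deposited. The log2 fold changes are shrunken toward 0, as read from the values. Features read in Mb alone show this: the deposited value was 2.63 for Smad6 with 5 reads but 1.25 for Thbs1 with 78, so deposited log2 fold changes do not rank features by size where reads lie in a single library. Feature coordinates were not used here.

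Features carry Entrez gene identifiers, except the 8 Bcl2l11 features, which are named as Bim seeds. Of the identifiers, 2540 matched the RefSeq gene table of assembly GRCm38.p6, which was used for symbols only because its build differs from those in the notes. This gave 242 features another symbol than the listed one, including 21 listed without a name. A gene can have several features, and 3 rows repeat another row exactly. All were kept.

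The planned test for a table of this kind took the authors' log2 fold change, p and adjusted p as deposited, at an adjusted p of 0.05. The table as used here holds no adjusted p or standard error. Benjamini-Hochberg adjustment was therefore computed over all 2548 features, without independent filtering. Standard errors were derived as the log2 fold change divided by the normal quantile of its p, which assumes a Wald test, and 95% intervals from them.

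Each deposited mean is a sum of whole reads, each weighted by 1 library's size factor, and is printed to 15 digits. The weights of the 4 libraries were found from the lowest means, and every combination of whole reads that gave a feature's mean was searched for. All 2548 features (100.0%) had exactly 1 solution, with a largest misfit of 6.25e-13 normalized reads. As a control, the 2165 lowest means were shifted by a relative amount of up to 1e-06, and none had a solution. In a simulation that left out the highest means, 2238 of 2238 features were recovered exactly. Neither check covers the features with the highest means. Every feature had at least 5 reads in at least 1 library. The size factors were 3.68 for Wa, 1.09 for Wb, 0.618 for Ma and 0.452 for Mb. The side of each library comes from the authors' comparison: of the ways to split 4 libraries into pairs, the one used gave the sign of the deposited log2 fold change for 98.8% of features, and the others for 67.4% and 32.4%. The sides are those of the authors' comparison, so a wrong label in it would carry over. Which replicate each recovered library is cannot be read from the table. Recovered reads were used to describe libraries and for alternatives chosen after seeing the data, and the main values are the authors'.

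Gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3, on the signed normal quantile of the deposited p, with an inter-gene correlation of 0.01. Each gene was represented by its feature with the highest mean. Of 20 lists fixed before the data were examined, 8 had 5 or more measured genes and were tested, with Benjamini-Hochberg adjustment over the 8. List medians were also set against 10000 random lists matched on mean in 10 bins. Members were adjusted over the list alone as well. Genes to be named were fixed before the data were examined: every Bcl2l11 feature, the features past the threshold with the largest changes or, with fewer than 5 in a direction, the 5 with the smallest p, up to 4 members of each list by p, and the 5 features with the highest means. This named 55 features. Any other gene was chosen after its values were seen. Some values that this rule would name are not reported here.

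Alternatives fixed beforehand were other thresholds, a minimum change, a restriction to features at or above the median mean, an empirical null for the deposited statistics (scaled by 0.903, their robust spread), and for lists a rank version, another correlation and a mean over all features of a gene. Chosen after seeing the data were limma's voom on recovered reads, with size factors setting the library sizes and at least 5 reads per feature, the same without each library in turn, and an estimated inter-gene correlation. Where a library was left out, the lone library on its side was assumed to vary like the pair on the other. voom adds 0.5 to each read number, which lifts features with few reads more in the shallow mutant-side libraries than in Wa. limma-trend on log2 normalized reads was run first, and voom replaced it after its output was seen: features with 0 reads in several libraries have no spread there, and on simulated reads limma-trend recovered 0 of 100 features changed 16-fold and gave 8.48% of unchanged features an unadjusted p under 0.05. voom with at least 20 and at least 50 reads per feature was tried as well, and the counts of all these settings are given with the alternatives. On simulated reads with a dispersion of 0.3, voom called 3 unchanged features, and 4.86% of unchanged features had an unadjusted p under 0.05. voom was also run with every library thinned at random to the 14539 reads of Mb, 100 times, keeping features with at least 5 reads in some thinned library. With a dispersion of 0.1 voom recovered 53 of 100 features changed 4-fold and 87 of 100 changed 16-fold. The dispersion of the libraries is not known. Simulated changes were placed only in features above a minimum mean, and every library was drawn from the means of Wa, Wb and Ma. cameraPR was tested on simulated statistics. Other versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

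The summed reads limit precision. As a one-sided 95% limit, a count of 0 allows up to 3 reads; the exact intervals given for single libraries are 2-sided and reach higher. The 3 reads are 0.815 normalized reads in Wa, 2.76 in Wb, 4.86 in Ma and 6.63 in Mb. Log2 ratios of single libraries used 0.5 added to normalized reads.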

Results

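Ago2 binding to RNA was measured by PAR-CLIP in mouse B cell progenitor lines that had been transformed with Abelson virus, which carries an activated tyrosine kinase. PAR-CLIP feeds cells the photoreactive nucleoside 4-thiouridine, crosslinks RNA to bound protein with ultraviolet light and sequences the RNA fragments that come down with the protein. Ago2 is the Argonaute protein that carries microRNAs to their target transcripts, so the captured fragments mark microRNA target sites. The lines came from fetal liver. Of the 4 libraries, 2 were from wild-type lines and 2 from lines homozygous for a mutated Bim 3' UTR, and the labels call the 2 of each genotype biological replicates. Bim, encoded by Bcl2l11, is a BCL-2 family protein that promotes apoptosis. The comparison asks which Ago2-bound features differ when the Bim 3' UTR is mutated. No RNA levels were used here, so a difference in reads cannot be told apart from a difference in transcript amount.

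The authors' deposited table lists 2548 features of 1848 genes, with a mean over the 4 libraries, a log2 fold change of mutant over wild type and an unadjusted p for each. Whole reads per library were recovered from the deposited means for all 2548 features. Libraries Wa and Wb are those on the wild-type side of the authors' comparison, and Ma and Mb those on the mutant side; their replicate numbers are not known. Reads in the listed features came to 160207 in Wa, 38804 in Wb, 24625 in Ma and 14539 in Mb. The median feature held 13.0 reads in Wa, 4.0 in Wb, 2.0 in Ma and 2.0 in Mb. Intervals for single libraries below are exact 95% Poisson intervals and cover counting error only. With 2 libraries on each side, the deposited p-values rest on very few samples.

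Ago2 reads at the mutated gene itself were examined first. All 8 listed Bcl2l11 features, which the authors' deposited table names as numbered Bim seeds, had a log2 fold change below 0, and none passed an adjusted p of 0.05. The lowest values in the authors' deposited table were at seed 8, with a log2 fold change of -2.78 (standard error 1.38, unadjusted p = 0.0429), and at seed 9, with -2.74 (standard error 1.39, unadjusted p = 0.0494). Their adjusted p, from Benjamini-Hochberg adjustment of the authors' deposited table, was 0.561 and 0.563 over all features and no lower than 0.198 over the Bcl2l11 features alone. Seeds 8 and 9 together held 78 reads in Wa and 31 in Wb, against 2 in Ma and 0 in Mb. In normalized reads this was 21.2 (interval 16.8 to 26.5) in Wa, 28.6 (19.4 to 40.5) in Wb and 3.24 (0.392 to 11.7) in Ma. The count of 0 in Mb has an interval of 0 to 8.16.

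Seed 5 was the Bcl2l11 feature with the highest mean, 82.5 normalized reads in the authors' deposited table. Its deposited log2 fold change was -0.84 (standard error 1.01, unadjusted p = 0.405). Its libraries did not separate by genotype: Wa held 49.7 normalized reads, Wb 168.6, Ma 14.6 and Mb 97.3. Wa and Wb differed from each other by more than their counting intervals, and so did Ma and Mb. The deposited log2 fold changes of the other Bcl2l11 features, seeds 1, 2, 3, 6 and 7, ran from -0.92 to -0.07, with unadjusted p from 0.502 to 0.952. The median over the 8 features was -0.84, at percentile 2.08 of 10000 random sets matched on mean, a description only, since features of one transcript are not independent. By library, the median log2 ratio to the wild-type mean was -0.32 in Ma, at percentile 40.6, and -2.89 in Mb, under the central 95% of the random sets. In Mb 6 of the 8 features had 0 reads, so its median rests on the 0.5 added to normalized reads. At seeds 1, 2, 3 and 7 those zeros say little. The wild-type means there, from 1.60 to 4.15 normalized reads, lie under the 6.63 that a 0 in Mb allows. limma's voom on the recovered reads put 6 of the 8 features below 0 with all 4 libraries and 4 without Mb. The voom log2 fold change of seed 5 was -1.28 with all 4 libraries. It was -2.49 without Mb, 0.20 without Ma, -2.06 without Wa and -0.31 without Wb.

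**Figure D1:**
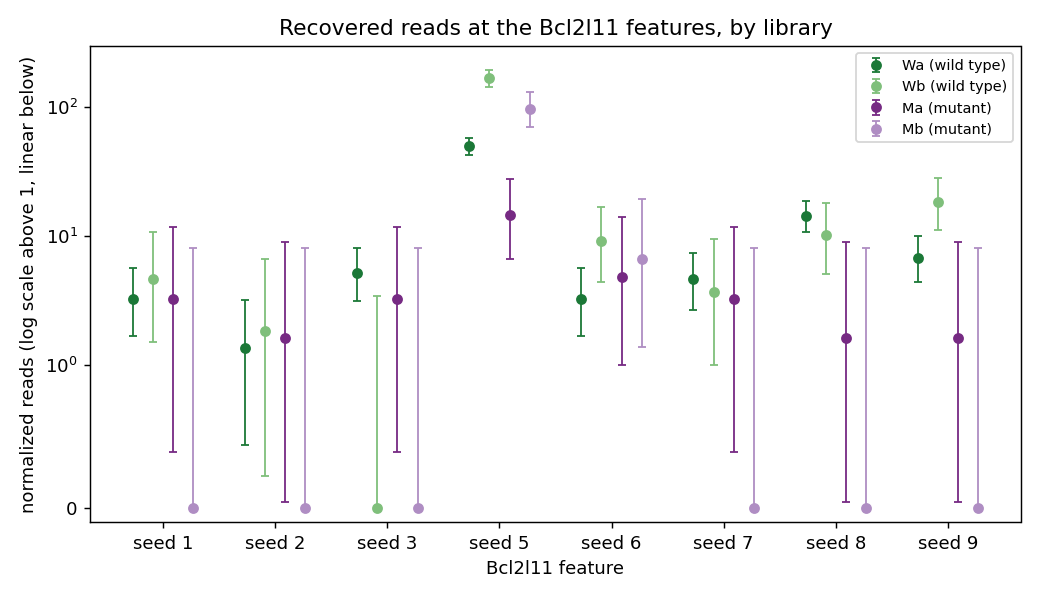
Normalized recovered reads (vertical axis, logarithmic above 1 and linear below) at each of the 8 Bcl2l11 features, with 1 point per library and bars for exact 95% Poisson intervals, which cover counting error only. At seeds 8 and 9 the mutant-side libraries Ma and Mb hold 1 read or none each, while at seed 5 Mb (97.3) lies between Wa (49.7) and Wb (168.6).

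Across all features, the mutant and wild-type lines showed no difference that survived correction for multiple testing. After Benjamini-Hochberg adjustment of the authors' deposited table, 0 of 2548 features passed an adjusted p of 0.05, and the smallest adjusted p was 0.165. At an unadjusted p under 0.05 the authors' deposited table held 216 features, 193 higher and 23 lower in the mutant, where 127.4 would be expected by chance. limma's voom on the recovered reads also gave 0 at an adjusted p of 0.05, with 75 higher and 4 lower at an unadjusted p under 0.05. limma-trend gave 0 too, with 17 higher and 33 lower. Its 0 adds little, since at an adjusted p of 0.05 it recovered 0 of 100 simulated features changed 16-fold. With every library thinned to the 14539 reads of Mb and features filtered again, to a median of 1355.5, voom gave 0. The median over 100 thinnings was 8 higher and 20 lower, so higher features no longer outnumbered lower ones in that fit. Thinning also discards reads and features, so these counts cannot tell an effect of depth from lost power. On simulated data of this design, with 2548 features, 2 against 2 libraries and a dispersion of 0.3, voom recovered 27 of 100 features changed 4-fold and 65 of 100 changed 16-fold. The changes were placed only in features above a minimum mean, and Mb was drawn from the means of the other libraries. These rates may therefore overstate power in the real libraries. Rescaling the deposited statistics to an empirical null passed 1 feature, Pkd2, at an adjusted p of 0.0245.

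The 5 features with the smallest p among those higher in the mutant were at Pkd2, Lsm8, Zfp740, F3 and Itpripl2, none of which passed an adjusted p of 0.05. Pkd2, which encodes the cation channel polycystin-2, had a log2 fold change of 5.57 in the authors' deposited table (standard error 1.39, unadjusted p = 6.47e-05). It held 1 read in Wa, 0 in Wb, 1 in Ma and 76 in Mb. F3, tissue factor, which starts blood coagulation, had 4.66 in the authors' deposited table (standard error 1.33, unadjusted p = 0.000443), with 44 reads in Mb and 1 in each of the others. Lsm8, part of the ring that binds U6 RNA, had 4.69 in the authors' deposited table and Itpripl2 4.87, with 32 and 20 reads in Mb against 3 and 1 in Ma. Zfp740, a zinc finger gene, differed from these in that both mutant-side libraries were high. Its log2 fold change in the authors' deposited table was 3.38 (standard error 0.94, unadjusted p = 0.00034), with 19.4 normalized reads in Ma and 28.7 in Mb against 1.63 in Wa and 1.84 in Wb.

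Among features lower in the mutant, the 5 smallest p belonged to Klhl14, Nfat5, Fbxo21, Xrcc2 and Tmem50b, and none passed an adjusted p of 0.05. Klhl14, a member of the Kelch-like family, had a log2 fold change of -3.32 in the authors' deposited table (standard error 1.16, unadjusted p = 0.0042, adjusted p = 0.531). It held 115 reads in Wa and 27 in Wb against 2 in Ma and 0 in Mb. Nfat5, a transcription factor of the response to high tonicity, had -1.88 in the authors' deposited table (standard error 0.78), with 145 and 74 reads on the wild-type side against 8 and 6. Fbxo21, an F-box gene, had -2.29 and Xrcc2, a gene of homologous recombination, -3.21 in the authors' deposited table. Tmem50b, at -2.26, held 26 reads in Ma and 2 in Mb against 307 in Wa and 221 in Wb.

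**Figure D2:**
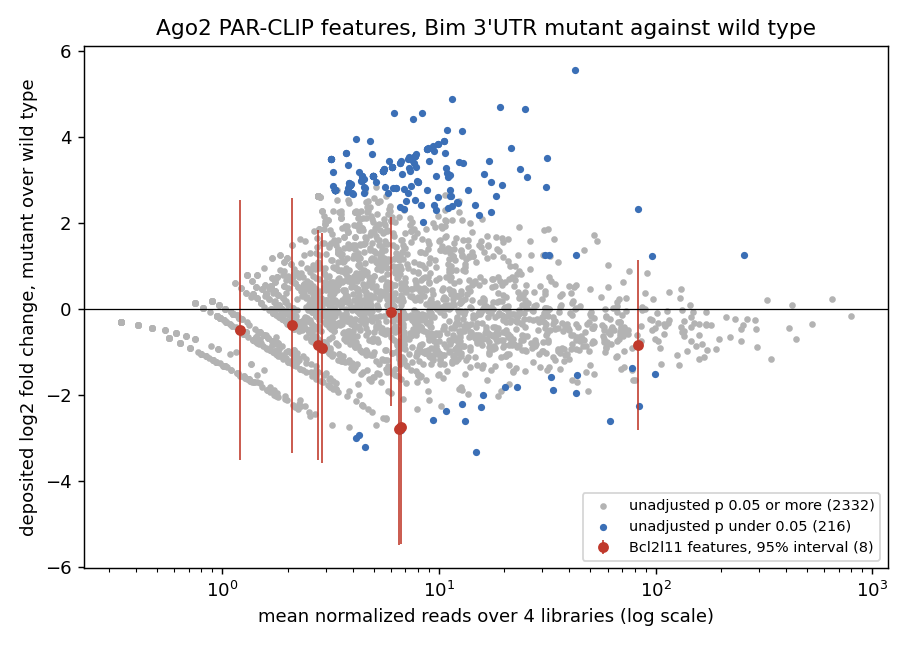
Deposited log2 fold change of mutant over wild type (vertical axis) against the mean normalized reads over the 4 libraries (horizontal axis, log scale) for 2548 features. Blue points are the 216 features at an unadjusted p under 0.05, 193 of them above 0, and red points with 95% intervals are the 8 Bcl2l11 features, all below 0.

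The mutant-side libraries did not contribute alike to these features. Of the 193 features counted as higher, Mb lay above both wild-type libraries in 192 and Ma in 70, and 87 had 0 reads in Wa, Wb and Ma together. The median log2 ratio to the wild-type mean over the 193 was 4.93 in Mb and 0.00 in Ma, with 0.5 added to normalized reads; 112 of the 193 had 0 reads in Ma, and Ma lay below both wild-type libraries in 6. Of the 23 counted as lower, Ma lay below both wild-type libraries in 23 and Mb in 22, with median log2 ratios of -2.08 in Ma and -3.34 in Mb. Across features, which are not independent replicates, log2 normalized reads correlated at 0.80 between Wa and Wb, 0.83 between Wa and Ma and 0.74 between Wb and Ma. Library Mb correlated with Wa at 0.14, with Wb at 0.26 and with Ma at 0.22. With every library thinned to 14539 reads, medians over 100 thinnings were 0.155, 0.258 and 0.227 for Mb with Wa, Wb and Ma. They were 0.657 between Wa and Wb, 0.692 between Wa and Ma and 0.657 between Wb and Ma. The features include 131 read in Mb alone, against 61 in Wa alone, and such features can lower a correlation. Without Ma, voom set Mb alone against the wild-type libraries and passed 329 features as higher and 26 as lower at an adjusted p of 0.05. That count depended on the setting: it was 12 with voom on features of at least 20 reads, 0 on those of at least 50 reads and 0 with limma-trend. Without Mb, Ma alone against the wild-type libraries gave 0, with 30 higher and 4 lower at an unadjusted p under 0.05.

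**Figure D3:**
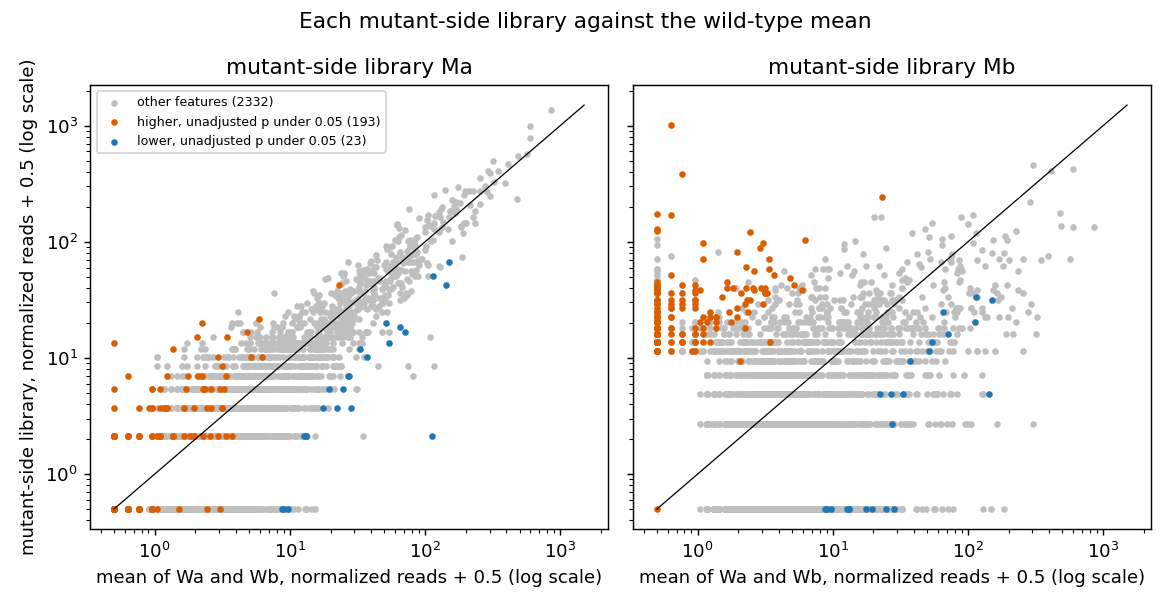
Normalized reads plus 0.5 in mutant-side library Ma (left) and Mb (right) against the mean of the wild-type libraries Wa and Wb, both axes logarithmic, 1 point per feature and a line of equality. The 193 features counted as higher (orange) lie mostly on or above the line in Ma, with a median log2 ratio of 0.00 set by features without reads, and lie far above it in Mb, with 4.93, while the 23 counted as lower (blue) lie below it in both.

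Gene lists fixed before the data were examined were compared next, with 1 feature per gene. Targets of the miR-17 cluster, which encodes several microRNAs and has Bim among its best-studied targets, were represented by 39 genes, 17 with a deposited log2 fold change above 0 and 22 below. The mutated gene Bcl2l11 was itself among the 39, through seed 5. The median over the list was -0.30, at percentile 29.9 of 10000 random lists matched on mean, and cameraPR gave an adjusted p of 0.375. The libraries differed here: the median log2 ratio to the wild-type mean was -0.40 in Ma, at percentile 2.47, and -0.29 in Mb, at percentile 87.6. Without Mb the list's voom median was -0.39. None of the 39 passed, adjusted over all features or adjusted over the list alone. In the authors' deposited table Socs3, a feedback inhibitor of cytokine signalling, had a log2 fold change of -1.53 (standard error 0.73, unadjusted p = 0.0362). Rb1, the retinoblastoma protein, had -2.58 in the authors' deposited table (standard error 1.26, unadjusted p = 0.0405). Thbs1, the matrix protein thrombospondin, had 1.25 in the authors' deposited table (unadjusted p = 0.0392), with 78 reads in Mb and 0 in every other library. Smad6, an inhibitory SMAD, had 2.63 on 5 reads, all in Mb.

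Of the BCL-2 family, 5 genes were measured, 3 above and 2 below 0, with a median log2 fold change of 0.04 and a cameraPR adjusted p of 0.965, and none passed, also when adjusted over the list alone. Besides Bcl2l11, the authors' deposited table gave 1.09 (standard error 0.76) for Bbc3, the p53-induced death activator PUMA, 0.71 (standard error 0.87) for the survival factor Mcl1 and -1.83 (standard error 1.51) for Bmf. The 8 measured p53 target genes were split 5 above to 3 below 0, with a median of 0.14 and a cameraPR adjusted p of 0.733. Among them the authors' deposited table gave 0.85 for Phlda3, 1.49 for Trp53inp1 and -0.46 for Ccng1, and none passed, also when adjusted over the list alone.

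B lineage genes lay mostly below 0, but the list did not pass. Of 12 measured, 10 had a deposited log2 fold change below 0, with a median of -0.48 and a cameraPR adjusted p of 0.141. With voom on the recovered reads the list had an adjusted p of 0.0425, and with an estimated inter-gene correlation an adjusted p of 0.668. The lowest values were in library Mb, in which the 12 genes together held 35.4 normalized reads, against 260.6 in Wa, 234.0 in Wb and 259.0 in Ma. Ikaros (Ikzf1), the cytokine receptor gene Kit, the recombinase gene Rag1 and the interleukin receptor gene Il7r were among 7 genes with 0 reads in Mb, and were named after their values were seen. Ikzf1 held 326 reads in Wa, 42 in Wb and 68 in Ma, and Irf4, also at 0 in Mb, 73, 67 and 17. For Kit, Rag1, Il7r, Syk and Bcl11a, all at 0 in Mb, the 0 says little. Their means of 5.53, 2.11, 1.77, 3.10 and 1.35 normalized reads lie under the 6.63 that a 0 in Mb allows. In the authors' deposited table Bach2, a repressor in B cells, had a log2 fold change of -1.42 (standard error 0.95), Irf4 -1.24 (standard error 1.19), Mef2d -0.98 and the kinase gene Syk -1.78. None of the 12 passed, adjusted over all features or adjusted over the list alone. Without Mb the list's voom median was -0.24 with an adjusted p of 0.934.

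Cell cycle genes lay below 0 in 13 of 17 cases, with a median deposited log2 fold change of -0.50 and a cameraPR adjusted p of 0.141. Rb1, Ccnd2 and Wee1, among others, are also on the list of miR-17 cluster targets, so these lists are not independent. Rb1 had -2.58 in the authors' deposited table (standard error 1.26, unadjusted p = 0.0405). The list had an adjusted p of 0.0425 with voom on the recovered reads and an adjusted p of 0.668 with an estimated inter-gene correlation. Cyclin D2 (Ccnd2) had -1.42 in the authors' deposited table (standard error 0.98) and cyclin E2 (Ccne2) -1.17 (standard error 0.98), while Wee1, the kinase that restrains entry into mitosis, had 1.03 (standard error 0.80). None passed, also when adjusted over the list alone. Without Mb the list's voom median was -0.39, with an adjusted p of 0.0955. Its median log2 ratio to the wild-type mean was -0.44 in Ma, at percentile 7.38 of the random lists, and -0.61 in Mb, at percentile 67.8.

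The remaining lists with at least 5 measured genes did not pass, and no member passed an adjusted p of 0.05, also when adjusted over the list alone. PI3K-AKT-FOXO pathway genes had a median log2 fold change of 0.07 over 15 genes, with a cameraPR adjusted p of 0.965. Pdpk1, a kinase that activates AKT, had 1.89 in the authors' deposited table (standard error 1.40, unadjusted p = 0.176), and Sgk1, a related kinase, 0.97 (standard error 0.90). Genes of the microRNA pathway had a median of -0.22 over 13 genes, with a cameraPR adjusted p of 0.602. Among them the RNA helicase gene Ddx6 had -2.74 in the authors' deposited table (unadjusted p = 0.0664), and the deadenylase gene Cnot6 had 2.48 (unadjusted p = 0.0914). MYC and RAS regulated growth genes had a median of -0.42 over 10 genes, with a cameraPR adjusted p of 0.157. Their median log2 ratio to the wild-type mean was -1.01 in Ma, at percentile 1.36 of the random lists, and -0.34 in Mb, at percentile 54.2. Jak1, a cytokine receptor kinase, had -1.36 in the authors' deposited table (standard error 0.68, unadjusted p = 0.0441), and Socs1 -1.29 (standard error 1.05).

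Some lists were too small to test. Of the stromal and hepatocyte markers, Vim, the intermediate filament vimentin, had a log2 fold change of 2.84 in the authors' deposited table (standard error 1.06, unadjusted p = 0.0073). Vim passed when adjusted over the list alone, at 0.0147, and not over all features, at 0.561. Its reads were 15 in Wa, 8 in Wb, 6 in Ma and 47 in Mb. The platelet-derived growth factor receptor gene Pdgfra, the other measured member, had 1.24 on 26 reads, all in Mb. Bcl11b, the only measured T and NK cell marker, had 3.85 in the authors' deposited table (standard error 1.35, unadjusted p = 0.0044), on 18 reads, all in Mb. As the only member it needs no adjustment over its list, and it did not pass over all features, at 0.531. Of ribosomal protein genes, Rpl15 had -3.01 (unadjusted p = 0.0372) and Rps24 0.46 in the authors' deposited table. The other 9 lists had 0 measured genes, among them histone, mitochondrially encoded, myeloid and erythroid genes and every microRNA list.

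The features with the highest means were at Gigyf1, a translational repressor, Dnajb9, a chaperone of the endoplasmic reticulum with 2 such features, the fatty acid elongase gene Elovl5 and the TGF-beta receptor gene Tgfbr2. Gigyf1 had a mean of 798.6 normalized reads and a log2 fold change of -0.17 (standard error 1.06) in the authors' deposited table. The log2 fold changes of Dnajb9 in the authors' deposited table were 0.23 (standard error 0.82) and -0.35 (standard error 0.92). Elovl5 had -0.71 (standard error 1.01) and Tgfbr2 0.08 (standard error 0.60). Over all features the median deposited log2 fold change was -0.07, with 47.5% of features above 0. Among features with a mean at or above the median of 4.85 normalized reads it was -0.09, with 46.4% above 0.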

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

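The voom and limma-trend fits, the fits without single libraries and the estimated correlation were chosen after seeing the data; the other settings were fixed beforehand. The count at an adjusted p of 0.05 stayed at 0 under the other thresholds, a 2-fold minimum, features at or above the median mean, and with every fit of all 4 recovered libraries. Of these fits, limma-trend adds little, since it recovered no simulated change at that threshold. The count was 1 under the empirical null, whose narrower scale lowers every p. Without single libraries it ran from 0 to 355, the 355 being voom without Ma, when Mb stands alone for the mutant. This fell to 12 with at least 20 reads per feature and 0 with at least 50, and limma-trend gave 0 without Ma but 163 without Wb. Features higher at an unadjusted p under 0.05 (193) numbered 267 under the empirical null, 117 at or above the median mean, where fewer are tested, 75 with voom (21 with at least 20 reads, 1 with at least 50), 8 with voom at equal depth, 17 with limma-trend, and 0 to 474 without single libraries: with voom 474 without Ma and 30 without Mb. Features lower (23) numbered 42 under the empirical null, 4 with voom (1 with at least 20 reads, 0 with at least 50), 20 with voom at equal depth, 33 with limma-trend, and 0 to 429 without single libraries: with voom 113 without Ma and 4 without Mb, with limma-trend 429 and 184. With all 4 libraries more features were thus higher than lower in voom at the depths as sequenced, and fewer in limma-trend and in voom at equal depth.

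No Bcl2l11 feature passed an adjusted p of 0.05 in any setting in which it was tested. Their number below 0 was 6 with voom and ran from 4 (without Mb) to 6, with 6 of the features left to test without Wa. It was 7 with limma-trend, and 6 without Ma as without Mb. With voom on at least 20 reads it was 5 of the 6 tested, also without Mb, and 3 of 5 without Ma; with at least 50 reads it was 2 of 2, also without Mb, and 1 of 2 without Ma. With voom, seed 3 had 0.060 and seed 6 had 0.26; the other 53 of 55 named features kept their direction.

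List medians changed sign in several settings: the BCL-2 family to -0.35 with means over all features of a gene and -0.17 with voom, also with an estimated correlation, and the microRNA pathway to 0.24 at or above the median mean and 0.18 with means over all features. Without single libraries the ranges were -0.016 to 0.66 for the BCL-2 family, -0.19 to 0.78 for p53 targets, -0.20 to 0.38 for the PI3K-AKT-FOXO pathway, -0.74 to 0.31 for the microRNA pathway and -1.08 to 0.029 for MYC and RAS regulated growth. With voom the B lineage list (-1.04) and the cell cycle list (-0.48) passed at an adjusted p of 0.0425, but had 0.668 on the same reads with an estimated correlation; without single libraries their adjusted p ran from 0.0555 to 0.934 and from 0.0635 to 0.186. The cause of these changes was not tested. The BCL-2 family had too few genes at or above the median mean, and without Wa, to test.

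No paired analysis was possible because the table holds no values per replicate and the recovered libraries carry no replicate numbers. The count tests planned for a table of counts were not run for the same lack of columns. Depth limits the shallow libraries: 25.2% of features had 0 reads in Mb, 23.7% in Ma and 18.1% in Wb, against 7.10% in Wa.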

Other observations

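All tests in this part were chosen or changed after the result was seen. Apart from Thbs1, the genes named in the next paragraph were chosen after their values were seen.

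Mb alone held reads for 131 features, against 61 for Wa, 1 for Wb and 1 for Ma, although its 14539 reads were the fewest. The features read only in Mb were led by Thbs1 (78 reads), Igfbp3 (58), Arrdc4 (56), Epha4 (48) and Ccn2 (42). Igfbp3 binds insulin-like growth factors, Epha4 is an ephrin receptor and Ccn2 is a connective tissue growth factor. Of 114 genes in a list of mesenchymal genes, 14 were measured, and 10 of these were read only in Mb. That list was not among the 20 lists fixed before the data were examined. B lineage genes held 16 reads in Mb, 11 of them at Tcf4. Features read only in Wa were led by Vldlr with 23 reads. Ddx3y, a gene of the Y chromosome, was the feature read only in Ma, with 8 reads.

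In the authors' deposited table more features lay higher than lower in the mutant at an unadjusted p under 0.05 (193 against 23). Lower depth of the mutant-side libraries may set that direction, which stays open. With every library thinned to 14539 reads, voom gave a median of 8 higher and 20 lower over 100 thinnings, with more lower in all 100. The thinnings share the same reads of Mb and test fewer features, which lowers power, and the deposited p could not be recomputed this way. The direction also turned without thinning in limma-trend, which gave 17 higher and 33 lower. Depth does not explain that Mb holds other features, since after thinning 189 to 217 features were read only in Mb and at most 7 only in any other library. A response shared by both mutant lines stays open: of the 193, Ma lay above both wild-type libraries in 70 and below both in 6, but 112 had 0 reads in Ma. At the 87 with 0 reads in Wa, Wb and Ma, Ma could not lie below the wild-type libraries, so the 6 says little. The median log2 ratio to the wild-type mean over the 193 was 0.00 in Ma, set by features without reads, and 4.93 in Mb. RNA of mesenchymal cells in Mb stays open too, since genes read in Mb alone are listed only because of Mb, and the 4 listed mesenchymal genes with at least 5 reads in another library, too few to decide, had a median log2 ratio of Mb to the mean of the others of 0.32; loss of B cell character and a wrong sample were not tested.

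All 8 Bcl2l11 features lay below 0 in the authors' deposited table. Whether that direction rests on Mb stays open. With voom 2 of the 8 were at or above 0 with all 4 libraries and 4 without Mb. Seed 5 had -2.49 without Mb but 0.20 without Ma, and -0.31 without Wb. Over the 8 features Ma held 34.0 normalized reads against 88.6 in Wa, 216.5 in Wb and 103.9 in Mb. Leaving seed 5 out, it was 19.4 in Ma against 38.9 in Wa, 47.9 in Wb and 6.63 in Mb. Whether Mb alone sets the low values of seeds 8 and 9 stays open too. Without Mb their mean log2 fold change was -2.26. Its upper 95% bound was 0.84, taken with the average standard error of the seeds, as if they varied together. Ma held 2 reads there, or 3.24 normalized reads (interval 0.392 to 11.7). That lies below the intervals of Wa (16.8 to 26.5) and Wb (19.4 to 40.5), which cover counting error only, and Ma is a single library. Reads of mutated sites could also be lost in mapping to an unmutated genome: Ma held reads at all 8 features and both mutant-side libraries at 2, and which features hold mutated bases is not given in the sources used here. Lower binding at mutated microRNA sites, which the design names, was not tested.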
